A study of Saccharolobus islandicus with 18 samples.

How the data were processed

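Total RNA was measured by sequencing in 18 libraries of Saccharolobus islandicus REY15A, strain E233S, a genetic host with a deletion at the pyrEF locus. Per the labels, cultures grew at 75 °C and were held in G2 with 6 mM acetic acid for 6 h, and the acid was then removed by pelleting and washing the cells before they went back into fresh warm medium. Samples were taken at 0, 1, 2, 3, 4 and 5 h after this release, with 3 libraries per hour. RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The labels do not say whether the 3 replicates of an hour were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

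Reads were aligned with HISAT2 2.0.5, per the submitters' processing notes. The counting tool, the annotation release, the strand setting and the authors' test are not given in the sources used here. The read counts per gene are deposited as whole numbers with 1 column per library, per the file headers. The deposited FPKM values, per the file headers, are also given per library. They equalled each count divided by gene length and by 1 factor per library, and these factors were proportional to DESeq2 size factors. The deposited table holds the authors' log2 fold change of each hour against 0 h, per the file headers. It also holds the authors' adjusted p-value of each of these 5 comparisons. Gene positions and products were taken from the deposited table, which places the genes on the REY15A chromosome, with positions counted from 1. The reference table of gene names covers strain M.16.4, so it was not used here, and genes carry the identifiers and products of the deposited table.

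Counts were analysed with edgeR 4.0.16 in R 4.3.3. The table holds 2781 genes. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 2476 tested and 305 out, of which 32 had 0 counts in all libraries. Libraries were scaled with TMM factors. A quasi-likelihood model with the hour as a factor was fitted to all 18 libraries together. The time course was tested with an F-test over the 5 hours against 0 h. Each hour was then compared with 0 h, and each hour with the hour before it, in 9 two-sided contrasts. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Expression levels are given as CPM (counts scaled to a common library total by the cpm function of edgeR) on the TMM scale, as mean and SD of 3 libraries. Logged CPM values used a prior count of 2. The peak hour of a gene called in the time course is the hour with the highest mean log2 CPM, and no test was made of it.

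Gene lists were written as name patterns before the data were examined: cell division, origin initiators, chromosome segregation, replication fork, dNTP supply, DNA repair, chromatin and topology, RNA polymerase and initiation, transcription regulators, signalling kinases, ribosomal proteins, translation factors, tRNA synthetases, chaperones, proteasome, archaellum and pili, S-layer, purine and pyrimidine synthesis, amino acid synthesis, TCA cycle and acetate use, respiration and ATP synthase, sugar transport, lipids, toxin-antitoxin, CRISPR-Cas, mobile elements, non-coding RNA species, and the deletion of the strain. Patterns were matched to gene names and products only for most lists. For the division, origin, segregation and aCcr1 lists they were also matched to the Pfam text and the family column. This choice, and 30 edits of single genes, were settled from the gene descriptions before any model was fitted. A list for aCcr1, the transcription factor in the title of the series, matched 0 genes, because the deposited products do not use that name and its locus tag could not be paired with the identifiers used. The 26 lists with at least 3 measured members were tested with camera in limma 3.58.1, two-sided, with the preset correlation of 0.01 between genes and adjustment over 234 tests. Counts of list members are also given adjusted over the list alone.

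Genes named in the text were chosen by a rule fixed with the lists. They are the 24 genes with the largest range of hourly means among those called in the time course, and for each hour the 8 highest and 8 lowest against 0 h. For each step between adjacent hours they are the 4 highest and 4 lowest. These genes had to be called, to have the 3 libraries of 1 hour fully apart from the 3 of the other, which chance gives for 10% of genes, to be protein-coding and not mobile, and to reach 20 CPM in a group. All measured members of the lists for division, origins, segregation and the strain deletion were added, and of every other list the 4 members with the smallest F-test p. The text gives a subset of these.

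The tests were run on simulated counts for the 2476 genes, in which 200 genes were changed by known folds at a dispersion of 0.01. For the 9 contrasts, 14 to 32% of genes changed 1.25-fold were recovered, 72 to 86% of those changed 1.5-fold, 90 to 98% of those changed 2-fold and 100% of those changed 4-fold. No recovered gene had the wrong sign, and 1.29 to 7.93% of the calls were false. For the simulated time course, 30%, 82%, 98% and 100% were recovered at these folds, with 6.63% of the calls false. For the simulated gene lists, the changed list had a camera p of 3.95e-72. All genes of that list were raised at least 2-fold, and the simulated genes varied independently. This result therefore does not test the preset correlation on lists whose genes vary together.

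The alternatives were DESeq2 size factors within edgeR, no filter on low counts, DESeq2 1.42.0, limma-trend on log2(FPKM + 1), a fit on the 2 groups compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation, the block and fry. Leaving out 4 h replicate 3 and 5 h replicate 3 together, leaving out libraries for single lists, and scaling to library totals alone were added after seeing the data. Groups of 3 libraries allow no exact permutation p below 0.1, so single genes were tested only through the model over all genes.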

Results

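Transcript levels were followed through 5 h after release of Saccharolobus islandicus from a block in G2, to ask which genes change as the synchronized cells go through division and the next round of replication. The 18 libraries fell into 6 groups of 3, at 0, 1, 2, 3, 4 and 5 h. Totals ran from 2896709 to 3974204 counts per library, and 2601 to 2652 of 2781 genes had at least 1 count. Totals were 2926985, 3338958 and 3257041 at 0 h, 3508404, 3075374 and 3520380 at 1 h, 3307550, 3358487 and 2897850 at 2 h, 2896709, 3391750 and 3974204 at 3 h, 3401585, 3691405 and 3186608 at 4 h, and 3418685, 3273802 and 3447482 at 5 h. The biological coefficient of variation over the tested genes was 9.45%. A single gene, SIRE_RS08185 (hypothetical protein), took 11.1 to 12% of the counts at 0 h and 19.7 to 21.4% at 4 h. With libraries scaled to their totals alone, a setting chosen after seeing the data, the median log2 fold change of all tested genes moved by -0.114 at 2 h, -0.103 at 3 h, -0.13 at 4 h and -0.111 at 5 h against 0 h, so the changes below are relative to the bulk of genes. All hours after 0 h were also hours after the removal of acetic acid and the change to fresh medium, and no sample without release was measured at those hours. Values written as a ± b are log2 fold changes ± SE from 3 libraries per group unless a level in CPM is given, where b is the SD.

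Over the time course, some of the widest changes were the fall of transcripts that were abundant in blocked cells and a rise at 1 h of single genes for the use of ammonium and sulfate. SIRE_RS03210 (DUF488 domain protein) stood at 359.5 ± 3.80 CPM at 0 h and 3.93 ± 1.14 CPM at 1 h, with an adjusted p of 2.69e-18 over the time course. SIRE_RS06760, a glutamate synthase family protein, went from 28.1 ± 1.47 CPM at 0 h to 481.4 ± 50.4 CPM at 1 h and 86.5 ± 9.81 CPM at 5 h. The reverse gyrase gene rgy (SIRE_RS05690), whose enzyme introduces positive supercoils into DNA, rose from 1951 ± 48.3 CPM at 0 h to 9334 ± 278 CPM at 2 h and stood at 3416 ± 209 CPM at 5 h. The homocitrate synthase gene lysS (SIRE_RS05610), of lysine synthesis, rose from 173.5 ± 12.3 CPM to 1727 ± 371 CPM at 4 h. By the edgeR F-test, 2071 of 2476 genes (83.6%) changed over the time course, and in 840 of them the hourly means spanned at least 1 log2 unit.

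Of the genes that changed, 648 were highest at 0 h, 416 at 1 h, 250 at 2 h, 118 at 3 h, 270 at 4 h and 369 at 5 h. All 3 genes of the cell division list and all 3 of the origin initiator list changed and peaked at 2 h. These lists hold only genes found by their descriptions. Known locus tags of ESCRT-III type and origin genes could not be paired with the identifiers used, so further division genes may have been measured without being listed. In the dNTP supply list, 5 of 5 members changed, of which 3 peaked at 2 h, and in the replication fork list 13 of 16 changed, of which 7 peaked at 2 h. In the TCA cycle and acetate list, 18 of 18 changed and 13 were highest at 0 h, and in the chaperone list 10 of 11 changed and 7 were highest at 0 h. Among tRNA synthetases, 20 of 21 changed and 12 peaked at 1 h. In the CRISPR-Cas list 26 of 29 changed, and 20 of these were highest at 5 h. In the sugar transport list 9 of 10 changed and 6 were highest at 5 h. Adjusted over the list alone, these counts were the same, at 3, 3, 5, 13, 18, 10, 20, 26 and 9. Ribosomal proteins, the list with the most measured members, had 45 of 65 members changed, or 38 adjusted over the list alone, with 26 highest at 5 h and 12 at 1 h.

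**Figure D1:**
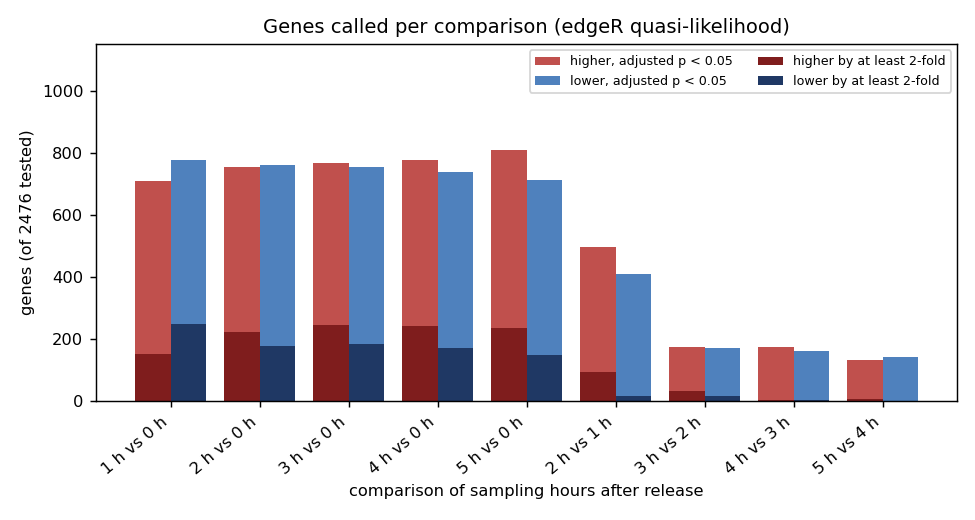
Number of genes called by edgeR in each comparison (bars from 0, of 2476 tested), with genes higher in red, genes lower in blue and genes changed at least 2-fold in the dark lower part of each bar. The 1 h vs 0 h step had 1487 calls, and the later steps between adjacent hours had 907, 347, 336 and 274.

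At 1 h against 0 h, the first hour after release, single genes for the use of ammonium and sulfate were among those that rose most, beside genes of other or unknown roles. SIRE_RS06760 rose by 4.10 ± 0.11 (adjusted p 1.66e-16) and glnA (SIRE_RS08300), glutamine synthetase, by 3.37 ± 0.10, from 346.8 ± 15.5 to 3586 ± 374 CPM. The ammonium transporter SIRE_RS05270 rose by 3.12 ± 0.16 and a further glutamate synthase, SIRE_RS06765, by 3.02 ± 0.11. Sulfate adenylyltransferase sat (SIRE_RS11720), which activates sulfate, rose by 3.46 ± 0.26, and the phosphoadenylyl-sulfate reductase SIRE_RS11725 by 3.78 ± 0.44. The transporter SIRE_RS02650 rose by 3.84 ± 0.13 and the hypothetical gene SIRE_RS08450 by 3.67 ± 0.10. A block of genes near 0.6 Mb of the chromosome fell, led by SIRE_RS03210 (-6.49 ± 0.18), SIRE_RS03215 (-6.33 ± 0.22), the metal-sulfur cluster assembly factor SIRE_RS03220 (-6.14 ± 0.22) and the hemerythrin domain protein SIRE_RS03195 (-6.10 ± 0.24). In all, 1487 genes were called, 710 higher and 777 lower, of which 151 and 248 changed at least 2-fold.

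Among the lists at 1 h, 22 of 44 amino acid synthesis genes rose and 7 fell (29 adjusted over the list alone), with a camera adjusted p of 0.0244 and an adjusted p = 0.495 with an estimated correlation. The tRNA synthetases had 12 of 21 higher and 3 lower (15 adjusted over the list alone), among them the methionine enzyme subunit metG (SIRE_RS07025, 1.89 ± 0.14) and the proline enzyme SIRE_RS07295 (1.01 ± 0.07), with adjusted p = 0.0474, and adjusted p = 0.481 with an estimated correlation. Ribosomal proteins had 20 of 65 higher and 2 lower (20 adjusted over the list alone), with adjusted p = 0.0139, and adjusted p = 0.481 with an estimated correlation. All 3 division genes rose (3 adjusted over the list alone), at adjusted p = 0.0396, and adjusted p = 0.449 with an estimated correlation. Of the TCA cycle and acetate genes 13 of 18 fell and 3 rose (18 adjusted over the list alone), at adjusted p = 0.02, and adjusted p = 0.481 with an estimated correlation. Those that fell include acetate--CoA ligase acs (SIRE_RS11860, -1.63 ± 0.14), which activates acetate, and the acyl-CoA synthetase SIRE_RS03490 (-1.96 ± 0.11). The CRISPR-Cas list had 17 of 29 lower and 3 higher (21 adjusted over the list alone), at adjusted p = 0.0306, and adjusted p = 0.471 with an estimated correlation. Its interference genes csa5 (SIRE_RS03875) and cas7a (SIRE_RS03880) fell by 2.17 and 2.14, while SIRE_RS04455 rose by 2.38 ± 0.15. Median log2 values of the ribosomal proteins against the 0 h mean were 0.34, 0.152 and 0.072 in the 3 libraries of 1 h.

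**Figure D2:**
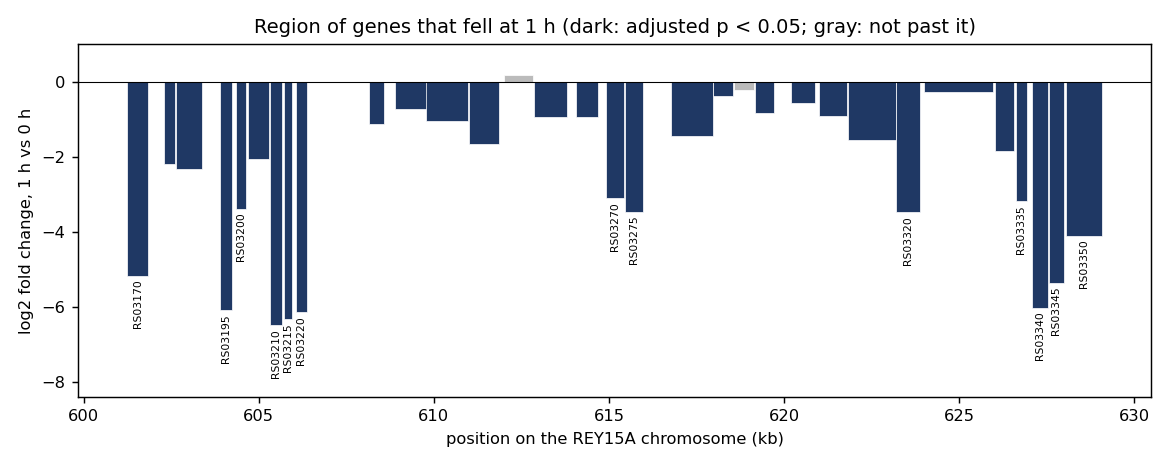
Log2 fold change at 1 h against 0 h by position on the REY15A chromosome (600 to 630 kb), with 1 bar per gene, dark where called and gray where not. Of 32 measured genes 30 were lower, down to -6.49 for SIRE_RS03210, and 0 were higher.

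**Figure D3:**
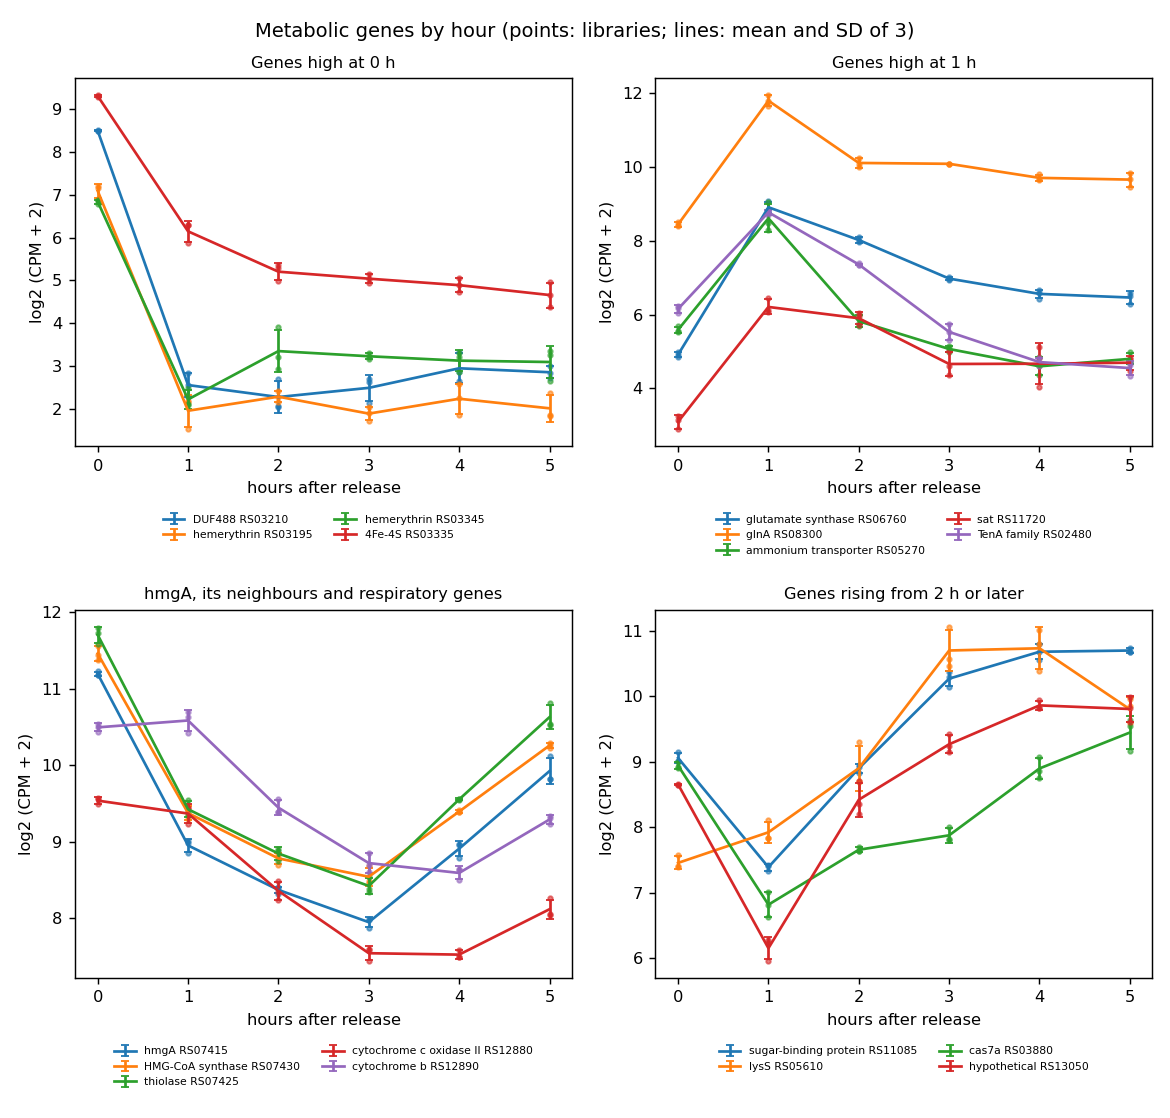
Expression of metabolic genes by hour after release, as log2(CPM + 2), with points for libraries and lines for the mean and SD of 3 libraries. The genes shown as high at 0 h fell by 1 h, glnA and the ammonium transporter were highest at 1 h, and hmgA and the 2 genes shown with it were lowest at 3 h (-3.25 against 0 h for hmgA).

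At 2 h against 0 h, genes of cell division, origin recognition and dNTP supply were higher, and replication fork genes went both ways. The division genes lie next to each other on the chromosome: the CdvA-like gene SIRE_RS05940 (1126025 to 1126741), the Snf7 family gene SIRE_RS05945 (1126760 to 1127539) of the ESCRT-III type, and SIRE_RS05950 (1127555 to 1128673), an ATP-binding protein with a Vps4-type domain. They rose by 0.82 ± 0.06, 1.35 ± 0.11 (adjusted p 5.3e-09) and 1.34 ± 0.08. The 3 genes with a CDC6-type domain, the family of archaeal origin initiators, rose by 1.52 ± 0.16 (SIRE_RS00005), 1.19 ± 0.11 (SIRE_RS06235) and 1.08 ± 0.07 (SIRE_RS08850). Reverse gyrase rgy rose by 2.26 ± 0.06, DNA polymerase I (SIRE_RS07370) by 1.46 ± 0.06, the sliding clamp subunit pcn (SIRE_RS08085) by 1.11 ± 0.07 and the replicative helicase MCM (SIRE_RS06220) by 0.98 ± 0.06, whereas flap endonuclease SIRE_RS09310 fell by 1.08.

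All 3 division genes rose at 2 h (3 adjusted over the list alone), with camera adjusted p = 0.0164, and adjusted p = 0.403 with an estimated correlation. All 3 origin genes rose too (3 adjusted over the list alone), with adjusted p = 0.0254, and adjusted p = 0.401 with an estimated correlation. In the dNTP supply list 4 of 5 rose and 0 fell (5 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.401 with an estimated correlation. Its members include the dCTP deaminases SIRE_RS09245 (1.86 ± 0.07) and SIRE_RS11600 (1.93 ± 0.16), thymidylate synthase SIRE_RS08520 (1.24 ± 0.07) and ribonucleotide reductase SIRE_RS05850 (1.09 ± 0.06). The replication fork list had 7 of 16 higher and 5 lower (12 adjusted over the list alone) and was not called, at adjusted p = 0.401. Purine and pyrimidine synthesis had 16 of 25 higher and 3 lower (19 adjusted over the list alone), at adjusted p = 0.0396, and adjusted p = 0.403 with an estimated correlation. Amino acid synthesis had 18 of 44 higher and 3 lower (19 adjusted over the list alone), at adjusted p = 0.0396, and adjusted p = 0.546 with an estimated correlation. Respiration and ATP synthase had 18 of 38 lower and 5 higher (23 adjusted over the list alone), at adjusted p = 0.0324, and adjusted p = 0.403 with an estimated correlation. The TCA cycle and acetate list had 13 of 18 lower and 3 higher (16 adjusted over the list alone), at adjusted p = 0.0257, and adjusted p = 0.481 with an estimated correlation.

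Other genes high at 2 h were the proteasome-activating nucleotidase SIRE_RS08775 (2.00 ± 0.12), which unfolds substrates of the proteasome, the transcription initiation factor IIB family gene SIRE_RS05790 (1.64 ± 0.07), the helix-turn-helix regulator SIRE_RS09625 (2.55 ± 0.09) and the ParA family gene SIRE_RS10010 (1.90 ± 0.10). The ribbon-helix-helix gene of the CopG family SIRE_RS00995 rose by 2.43 ± 0.11 at 2 h and 2.48 ± 0.11 at 3 h, and the deposited table does not say whether it is aCcr1. The hypothetical gene SIRE_RS00750 rose by 3.11 ± 0.10. At this hour 1516 genes were called, 755 higher and 761 lower, of which 223 and 177 changed at least 2-fold, and with totals alone 614 were higher and 908 lower (40.3% in place of 49.8%).

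**Figure D4:**
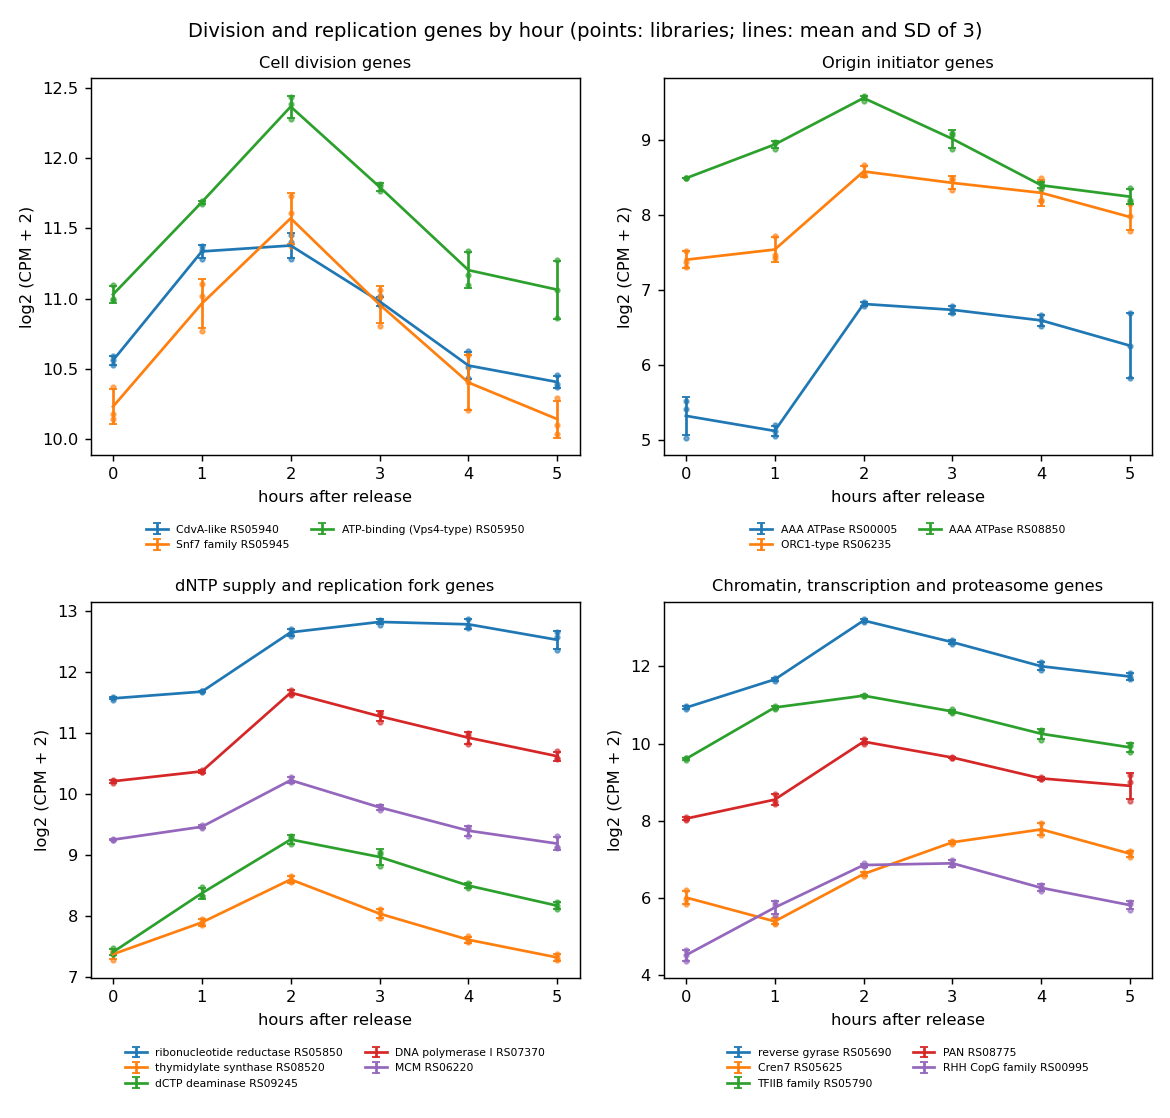
Expression of division, origin, replication, dNTP supply, chromatin and regulatory genes by hour after release, as log2(CPM + 2), with points for libraries and lines for the mean and SD of 3 libraries. The Snf7 family gene and its ATP-binding neighbour were highest at 2 h, and the chromatin protein Cren7 was highest at 4 h.

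At 3 h against 0 h, the genes hmgA, SIRE_RS07420, SIRE_RS07425 and SIRE_RS07430, which lie side by side, were at their lowest of the 6 hours. The gene lysS rose by 3.28 ± 0.19, the permease SIRE_RS03500 by 2.69 ± 0.19 and Cren7 (SIRE_RS05625), an abundant chromatin protein, by 1.45 ± 0.10. Of the early steps of the mevalonate pathway, which makes the isoprenoid chains of archaeal lipids, hmgA (SIRE_RS07415) stood at -3.25 ± 0.09, the thiolase SIRE_RS07425 at -3.29 ± 0.09, the hydroxymethylglutaryl-CoA synthase SIRE_RS07430 at -2.92 ± 0.07 and their neighbour SIRE_RS07420 at -3.26 ± 0.08. A later gene of the pathway, mvaD (SIRE_RS11425), rose by 0.57 ± 0.10, and the lipid list had 3 of 8 higher and 4 lower (7 adjusted over the list alone) and was not called, at adjusted p = 0.212. The Rieske protein SIRE_RS12875 fell by 1.96 and aconitase acnA (SIRE_RS05095) by 1.14. In all, 1521 genes were called, 767 higher and 754 lower, of which 244 and 185 changed at least 2-fold, and with totals alone the majority turned, with 630 higher and 874 lower (41.9% in place of 50.4%).

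Among the lists at 3 h, respiration had 17 of 38 lower and 5 higher (22 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.401 with an estimated correlation. The TCA cycle and acetate list had 13 of 18 lower and 2 higher (15 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.468 with an estimated correlation. Chaperones had 6 of 11 lower and 0 higher (6 adjusted over the list alone), at adjusted p = 0.039, and adjusted p = 0.407 with an estimated correlation. They include a CDC48 family ATPase (SIRE_RS09320, -1.03 ± 0.09) and a thermosome subunit (SIRE_RS06140, -0.98 ± 0.13), of families known to unfold or fold proteins. Amino acid synthesis had 23 of 44 higher and 2 lower (24 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.481 with an estimated correlation. The dNTP supply list had 4 of 5 higher and 0 lower (4 adjusted over the list alone), at adjusted p = 0.02, and adjusted p = 0.401 with an estimated correlation. All 3 division genes were still higher than at 0 h (3 adjusted over the list alone), at 0.42 ± 0.06, 0.73 ± 0.11 and 0.77 ± 0.08, but the list was not called, at adjusted p = 0.074.

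At 4 h against 0 h, the division genes did not differ from 0 h by the test, with -0.03 ± 0.06 for SIRE_RS05940, 0.18 ± 0.11 for SIRE_RS05945 and 0.18 ± 0.08 for SIRE_RS05950. By edgeR, 0 of these 3 were called, 0 adjusted over the list alone. Cren7 rose by 1.79 ± 0.10 and the regulators SIRE_RS09945 (ArsR family), SIRE_RS09950 (AbrB family) and SIRE_RS05030 (MarR family) by 1.76 ± 0.08, 1.76 ± 0.09 and 1.61 ± 0.06. The highest genes were lysS (3.31 ± 0.19), the nickel and cobalt transporter SIRE_RS02230 (2.98 ± 0.22) and SIRE_RS04525, an ATP-binding protein (2.83 ± 0.16). Cytochrome c oxidase subunit II (SIRE_RS12880), of the terminal oxidase, fell by 2.02, and cytochrome b (SIRE_RS12890) by 1.91. In all, 1513 genes were called, 776 higher and 737 lower (51.3% higher), of which 242 and 171 changed at least 2-fold, and with totals alone 608 were higher and 903 lower (40.2%).

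Respiration had 18 of 38 genes lower and 5 higher at 4 h (24 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.401 with an estimated correlation. Sugar transport had 7 of 10 higher and 0 lower (7 adjusted over the list alone), at adjusted p = 0.0388, and adjusted p = 0.471 with an estimated correlation. Its substrate-binding gene SIRE_RS11085 had fallen by 1.68 at 1 h and stood 1.63 ± 0.07 above 0 h at 4 h. The dNTP supply list had 4 of 5 higher and 0 lower (4 adjusted over the list alone), at adjusted p = 0.0419, and adjusted p = 0.401 with an estimated correlation. Chaperones had 6 of 11 lower and 0 higher (6 adjusted over the list alone), at adjusted p = 0.0492, and adjusted p = 0.449 with an estimated correlation. The TCA cycle and acetate list had 13 of 18 lower and 3 higher (16 adjusted over the list alone), at adjusted p = 0.0474, and adjusted p = 0.515 with an estimated correlation. Of the ribosomal proteins 22 of 65 rose and 1 fell (17 adjusted over the list alone), and they were not called as a list, at camera adjusted p = 0.074. Their median against 0 h was 0.255 in 4 h replicate 3, where rRNA took 0.965% of the counts, and 0.118 and 0.074 in replicates 1 and 2, with rRNA at 0.599 and 0.638%.

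At 5 h against 0 h, 20 of 29 CRISPR-Cas genes and 36 of 65 ribosomal proteins were higher, and 20 of 38 respiration genes were lower. The nickel and cobalt transporter SIRE_RS02230 rose by 2.75 ± 0.22, the hypothetical gene SIRE_RS10690 by 2.61 ± 0.22, the cytosine permease SIRE_RS02840 by 2.43 ± 0.15 and lysS by 2.37 ± 0.19. The gene cas7a, at -2.14 ± 0.12 at 1 h, stood at 0.52 ± 0.11 at 5 h. The FAD-dependent oxidoreductase SIRE_RS00350 stood at -4.39 ± 0.22 and the 4Fe-4S protein SIRE_RS03335 at -4.74 ± 0.14. The hypothetical gene SIRE_RS14205 fell by 5.30, but 24.5% of its length overlaps a gene on the opposite strand, so its counts are uncertain. In all, 1522 genes were called, 809 higher and 713 lower (53.2% higher), of which 237 and 150 changed at least 2-fold, and with totals alone 667 were higher and 899 lower (42.6%).

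In the CRISPR-Cas list 20 of 29 rose and 1 fell at 5 h (21 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.407 with an estimated correlation. Of the ribosomal proteins 36 of 65 rose and 4 fell (40 adjusted over the list alone), at adjusted p = 0.0306, and adjusted p = 0.515 with an estimated correlation. This count was 29, 31 and 27 without 0 h replicate 1, 2 or 3, 24, 19 and 45 without 5 h replicate 1, 2 or 3, and 44 without both 4 h replicate 3 and 5 h replicate 3, settings chosen after seeing the data. The median of the ribosomal proteins against 0 h was 0.028 in 5 h replicate 3, where rRNA took 0.699% of the counts, and 0.347 and 0.377 in replicates 1 and 2, with rRNA at 0.995 and 1.04%. Amino acid synthesis had 27 of 44 higher and 3 lower (30 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.471 with an estimated correlation. Sugar transport had 8 of 10 higher and 1 lower (9 adjusted over the list alone), at adjusted p = 0.032, and adjusted p = 0.464 with an estimated correlation. Respiration had 20 of 38 lower and 2 higher (22 adjusted over the list alone), at adjusted p = 0.00687, and adjusted p = 0.401 with an estimated correlation.

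**Figure D5:**
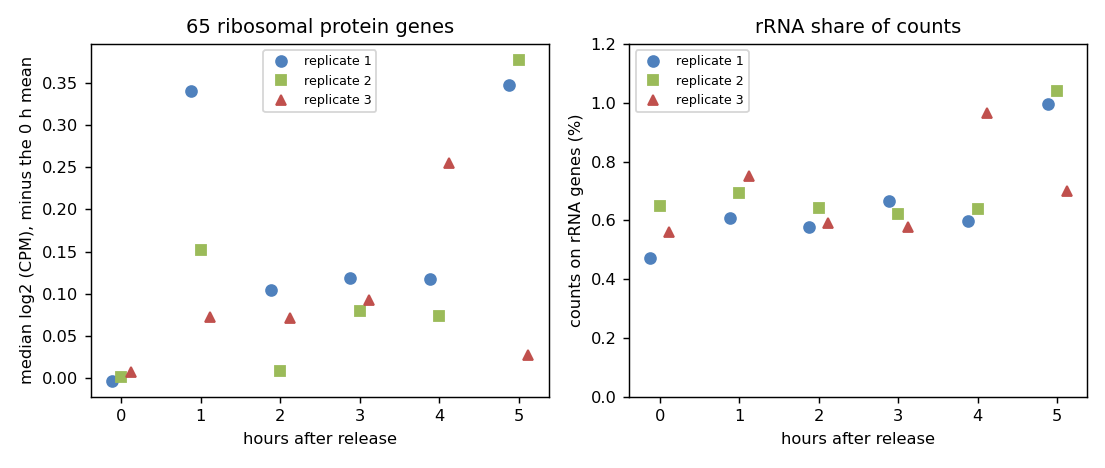
Median log2 CPM of 65 ribosomal protein genes minus their 0 h mean (left) and percent of counts on rRNA genes (right), by hour, with 1 point per library. In both, 4 h replicate 3 (0.255 and 0.965%) lies above its group and 5 h replicate 3 (0.028 and 0.699%) below its group.

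From 1 h to 2 h, origin and dNTP supply genes rose, and genes that had risen at 1 h parted. The ammonium transporter SIRE_RS05270 fell by 2.86 and glnA by 1.69, as did the hypothetical gene SIRE_RS08450 (-3.77 ± 0.10) and the acetyltransferase SIRE_RS12410 (-2.33 ± 0.10). The sulfate genes sat (-0.32 ± 0.20) and SIRE_RS11725 (-0.29 ± 0.32) were not called in this step. Rising genes were the hypothetical SIRE_RS13050 (2.31 ± 0.13), the enoyl-CoA hydratase family gene SIRE_RS13035 (2.08 ± 0.15), SIRE_RS03405, a DNA-binding protein (2.03 ± 0.21), and rgy (1.53 ± 0.06). The Snf7 family gene and its ATP-binding neighbour rose by 0.61 and 0.68 while the CdvA-like gene was at 0.04 ± 0.06. All 3 origin genes rose (3 adjusted over the list alone), at adjusted p = 0.00687, and adjusted p = 0.401 with an estimated correlation, and 4 of 5 dNTP supply genes rose (4 adjusted over the list alone), at adjusted p = 0.00303, and adjusted p = 0.401 with an estimated correlation. In all, 907 genes were called, 497 higher and 410 lower (54.8% higher), and with totals alone 414 were higher and 543 lower (43.3%).

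In the tRNA synthetase list 13 of 21 fell and 1 rose from 1 h to 2 h (16 adjusted over the list alone), at adjusted p = 0.003, and adjusted p = 0.401 with an estimated correlation. Of the ribosomal proteins 7 of 65 fell and 0 rose (3 adjusted over the list alone), at adjusted p = 0.0321, and adjusted p = 0.528 with an estimated correlation. Respiration had 18 of 38 lower and 8 higher (28 adjusted over the list alone), at adjusted p = 0.0268, and adjusted p = 0.403 with an estimated correlation. Sugar transport had 5 of 10 higher and 1 lower (7 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.403 with an estimated correlation. The CRISPR-Cas list had 8 of 29 higher and 1 lower (9 adjusted over the list alone), at adjusted p = 0.0476, and adjusted p = 0.481 with an estimated correlation.

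From 2 h to 3 h, all 3 division genes fell, by 0.40, 0.62 and 0.57 (3 adjusted over the list alone), at adjusted p = 0.00202, and adjusted p = 0.401 with an estimated correlation. The sulfate gene SIRE_RS11725 fell by 2.09, sat by 1.28 and the sulfurtransferase SIRE_RS11740 by 2.05, as did the TenA family gene SIRE_RS02480 (-1.87 ± 0.10). The gene lysS rose by 1.80 ± 0.18, the thiolase domain gene SIRE_RS13030 by 1.51 ± 0.19 and SIRE_RS03500 by 1.46 ± 0.18. Signalling kinases had 4 of 8 lower and 0 higher (4 adjusted over the list alone), at adjusted p = 0.00944, and adjusted p = 0.401 with an estimated correlation. Sugar transport had 4 of 10 higher and 0 lower (4 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.403 with an estimated correlation. Respiration had 6 of 38 lower and 1 higher (7 adjusted over the list alone), at adjusted p = 0.0396, and adjusted p = 0.407 with an estimated correlation. In all, 347 genes were called, 174 higher and 173 lower.

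From 3 h to 4 h, the division genes fell further, by 0.46, 0.55 and 0.59 (3 of 3, and 3 adjusted over the list alone), at adjusted p = 0.000597, and adjusted p = 0.401 with an estimated correlation. Of the genes beside hmgA, SIRE_RS07425 rose by 1.13 ± 0.08 and SIRE_RS07420 by 1.12 ± 0.07, and hmgA itself rose by 0.97 ± 0.08. The lipid list had 2 of 8 higher and 1 lower (3 adjusted over the list alone) and was not called, at adjusted p = 0.165. The thiamine synthesis gene SIRE_RS03820 (ThiC), which shares 10.9% of its length with another gene, rose by 1.40 ± 0.20. In the CRISPR-Cas list 12 of 29 rose and 0 fell (15 adjusted over the list alone), with cas7a at 1.03 ± 0.11, at adjusted p = 4.28e-06, and adjusted p = 0.401 with an estimated correlation. The replication fork list had 5 of 16 lower and 0 higher (6 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.403 with an estimated correlation. The dNTP supply list had 3 of 5 lower and 0 higher (3 adjusted over the list alone), at adjusted p = 0.0317, and adjusted p = 0.401 with an estimated correlation. The TCA cycle and acetate list had 2 of 18 higher and 0 lower (2 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.471 with an estimated correlation. In all, 336 genes were called, 175 higher and 161 lower (52.1% higher), and with totals alone 126 were higher and 185 lower (40.5%). The count was 222 without 3 h replicate 1 and 217 without 4 h replicate 2.

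From 4 h to 5 h, hmgA, its neighbours and 11 of 29 CRISPR-Cas genes rose. The oxidoreductase SIRE_RS11320 rose by 1.15 ± 0.18, SIRE_RS07425 by 1.08 ± 0.08 and hmgA by 1.02 ± 0.08, and the hypothetical gene SIRE_RS14730 fell by 1.10 and lysS by 0.95. The CRISPR-Cas list had 11 of 29 higher and 0 lower (16 adjusted over the list alone), at adjusted p = 0.000197, and adjusted p = 0.401 with an estimated correlation. The lipid list had 2 of 8 higher and 0 lower (2 adjusted over the list alone), at adjusted p = 0.0324, and adjusted p = 0.401 with an estimated correlation. Transcription regulators had 10 of 64 lower and 2 higher (15 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.407 with an estimated correlation, and dNTP supply had 4 of 5 lower and 0 higher (4 adjusted over the list alone), at adjusted p = 0.0139, and adjusted p = 0.401 with an estimated correlation. Ribosomal proteins had 6 of 65 lower and 0 higher (13 adjusted over the list alone), although their median was 0.087 and their mean 0.155. They were not called as a list, at camera adjusted p = 0.606. In all, 274 genes were called, 133 higher and 141 lower (48.5% higher), and with totals alone 180 were higher and 119 lower (60.2%). The count and the balance of directions depended on single libraries, with 131 (45 higher, 86 lower) without 4 h replicate 1, 139 (45 and 94) without 4 h replicate 2, 116 (36 and 80) without 5 h replicate 2 and 650 (385 and 265) without 5 h replicate 3. The count was 255 (118 and 137) without 4 h replicate 3 and 200 (79 and 121) without 5 h replicate 1. It was 49 (13 and 36) in a fit of these 2 groups alone and 634 (363 and 271) without both 4 h replicate 3 and 5 h replicate 3.

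The remaining lists were not called in any of the 9 contrasts, and their members moved both ways. In the segregation list 7 of 8 changed over the time course (7 adjusted over the list alone): the ParA family genes SIRE_RS00660 and SIRE_RS00665 fell by 1.25 and 0.94 at 1 h, SIRE_RS01460 rose by 0.76 and the ParB domain gene SIRE_RS09595 by 0.64 at 1 h, and SIRE_RS02400 rose by 0.84 at 5 h. In this list 1 gene was at least 2-fold higher at 2 h. The ParA family gene SIRE_RS10010, given above for 2 h, rose more than the segregation genes named here. Without 0 h replicate 2, SIRE_RS01460 stood at 0.52 and was not called, at adjusted p = 0.0579. The ParA family genes SIRE_RS00680 and SIRE_RS01335 were not called at 5 h, at 0.32 ± 0.14 and 0.14 ± 0.10. By limma-trend SIRE_RS00680 was called at 5 h (adjusted p = 0.0485). By edgeR it was called without 0 h replicate 2 (adjusted p = 0.0365) and without 5 h replicate 1 (adjusted p = 0.0377). In the chromatin and topology list 6 of 7 changed (6 adjusted over the list alone), among them albA (SIRE_RS05695, 0.76 ± 0.08 at 4 h). In the DNA repair list 13 of 15 changed (13 adjusted over the list alone), with the nuclease genes SIRE_RS00065 at 2.26 ± 0.19 at 3 h and SIRE_RS00465 at -1.12 ± 0.08 at 4 h, and its median was negative and its mean positive at each hour against 0 h. The proteasome list had 6 of 6 changed (6 adjusted over the list alone), and its median was also negative and its mean positive at each hour. The RNA polymerase list had 15 of 19 changed (14 adjusted over the list alone), with subunit G (SIRE_RS08750) at 1.31 ± 0.12 at 2 h.

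Translation factors had 14 of 14 changed (14 adjusted over the list alone), with infB (SIRE_RS08985) at -0.69 ± 0.06 at 2 h and the release factor SIRE_RS00695 at 0.78 ± 0.08 at 5 h. At 2 h and 4 h the median and mean of this list were negative and its test pointed up, and at 5 h its median was -0.034 and its mean 0.082. Toxin-antitoxin genes had 32 of 42 changed (32 adjusted over the list alone), among them the ParD family gene SIRE_RS08000 (1.75 ± 0.12 at 2 h) and the VapC family gene SIRE_RS13260 (-1.15 ± 0.11 at 4 h). At 3 h the toxin-antitoxin median was 0.062 and the mean -0.027. Archaellum and pili genes had 8 of 12 changed (8 adjusted over the list alone), led by SIRE_RS00910 (2.08 ± 0.08 at 1 h), of the type II secretion F family. Mobile elements had 19 of 37 changed (17 adjusted over the list alone), with the integrase SIRE_RS08260 at 1.95 ± 0.07 at 2 h. Non-coding RNA species had 10 of 17 changed (10 adjusted over the list alone), with 16S rRNA at 0.94 ± 0.14 at 5 h and the RNase P RNA rnpB at 0.80 ± 0.07 at 3 h. All rRNA genes together took only 0.472 to 0.648% of the counts at 0 h and 0.699 to 1.04% at 5 h. The 16S value may therefore not follow the level in the cells, and the share in 5 h replicate 3 was the lowest of its hour. The replication fork list had a median of 0.008 and a mean of 0 at 1 h. Medians and means also differed in sign for transcription regulators at 1 h, tRNA synthetases and the replication fork at 3 h, segregation at 5 h, respiration and DNA repair from 3 h to 4 h, the proteasome in the steps from 2 h to 3 h and 3 h to 4 h, and toxin-antitoxin genes from 4 h to 5 h. The DNA repair test pointed down from 1 h to 2 h, with a median of 0.02 and a mean of 0.061.

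The S-layer list had 2 measured genes, of which SlaB (SIRE_RS08180), a surface-layer anchor, rose by 1.00 ± 0.06 at 4 h and SIRE_RS05160 fell by 0.73 at 2 h. For the strain's deletion, the orotidine 5'-phosphate decarboxylase gene SIRE_RS07070 had 0 counts in all 18 libraries. This allows a mean of up to 3 counts in any 1 library taken alone, and a lower one over the 18 together. The orotate phosphoribosyltransferase gene SIRE_RS07075 rose by 0.81 ± 0.19 at 1 h and a further decarboxylase gene, SIRE_RS09180, rose by 0.39 ± 0.08 at 2 h. SIRE_RS07075 has the identifier after that of SIRE_RS07070. Counts per gene do not show whether it is intact in this strain, so its reads may come from a part left of the deleted locus. The other lists, transcription regulators, signalling kinases, amino acid synthesis, purine and pyrimidine synthesis, lipids and respiration, had 51 of 64, 8 of 8, 36 of 44, 24 of 25, 7 of 8 and 34 of 38 members changed over the time course, and 51, 8, 36, 24, 7 and 34 adjusted over the list alone. Of 234 list tests 48 were called with the preset correlation and 0 with an estimated one by limma's camera, where 28 had an unadjusted p below 0.05. The limma test fry, which asks only whether a list's genes move one way, called 147.

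The authors' own comparisons against 0 h, deposited with the counts, called 1372, 1467, 1506, 1485 and 1302 genes at 1, 2, 3, 4 and 5 h at an adjusted p below 0.05. Of these, 1339, 1412, 1441, 1418 and 1291 were also called here, with 0 opposite signs by either test.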

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

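Alternatives that left out 4 h replicate 3 and 5 h replicate 3 together, that left out libraries for the ribosomal protein and CRISPR-Cas lists, or that scaled libraries to their totals alone were chosen after seeing the data, and the others before. Of 161 alternative values for the main results, 151 stayed within 1.5 times the reported value and 10 did not. The number of genes called from 4 h to 5 h was 274 as reported, 49 in a fit of these 2 groups alone, where the spread comes from 6 libraries in place of 18, and 634 without 4 h replicate 3 and 5 h replicate 3, 248 of them among the 274. Without both, 321 genes were called from 3 h to 4 h. Leaving out 1 library at a time gave 116 to 650 for this step and 217 to 244 for the step from 3 h to 4 h (336 as reported). It gave 1986 to 2147 for the time course, 1352 to 1403 at 1 h, 1396 to 1429 at 2 h, 1403 to 1443 at 3 h, 1367 to 1417 at 4 h and 1390 to 1520 at 5 h against 0 h, 738 to 817 from 1 h to 2 h and 281 to 304 from 2 h to 3 h. The cause was not tested for the counts from 4 h to 5 h without single libraries. Of the list tests, 48 were called as reported, 0 with an estimated correlation (lowest adjusted p = 0.401) and 147 with fry, which does not compare a list with other genes. With the replicate number as a block, 2050 genes were called over the time course and 255 from 4 h to 5 h. The numbers did not pair the libraries. For 8 of 18 libraries, the mean correlation with libraries of other hours was highest for those of their own number. Over pairs of libraries, the median correlation was 0.006 for the same number and -5e-04 for other numbers.

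With totals alone, the called members of these lists had another majority than with TMM factors. RNA polymerase had 4 higher and 5 lower at 5 h, in place of 6 and 2. From 1 h to 2 h it had 4 and 6, in place of 5 and 2. Purine and pyrimidine synthesis had 6 and 7 from 1 h to 2 h, in place of 8 and 3. Sugar transport had 2 and 3 at 2 h (TMM 2 and 1), and toxin-antitoxin 10 and 11 at 4 h (TMM 13 and 11). At 5 h transcription regulators had 21 and 24 (TMM 23 and 18) and translation factors 5 and 7 (TMM 6 and 4). From 4 h to 5 h amino acid synthesis had 4 and 2 (TMM 1 and 2) and tRNA synthetases 2 and 1 (TMM 0 and 1). Of 3080 alternative values for the 161 named genes, 3075 kept their direction and their side of the threshold, 0 reversed, 1 was lost and 4 were gained. Most named genes were picked for large called changes or a small F-test p, so this says little about other genes. The lost and gained values were all in ParA family genes, named whatever their p. The lost value was SIRE_RS01460 at 1 h without 0 h replicate 2 (0.52, adjusted p = 0.0579). The gained values were SIRE_RS01335 at 3 h in a fit of the 2 groups, and otherwise SIRE_RS00680 at 5 h. The peak hour was the same for 2048 of 2071 genes with DESeq2 factors and for 1775 (85.7%) in at least 2 of the 3 replicate numbers. At this depth, simulated changes of 1.5-fold were recovered for 72 to 86% of genes in the 9 contrasts, so small changes can have gone uncalled. The simulation changed 200 of 2476 genes at a single dispersion of 0.01. In the data far more genes were called against 0 h (1487 at 1 h), and the spread within hours was not equal. The simulated rates of recovery and of false calls may therefore not hold for these contrasts.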

Other observations

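All tests of explanations below were chosen or redefined after the result was seen, except the regrouping of libraries and the thinning of counts to equal depth. Genes in the next paragraphs were chosen after their values were seen.

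A set of genes followed the Snf7 family and ATP-binding division genes (SIRE_RS05945 and SIRE_RS05950) through the 6 hours. Of the 840 genes with a range of at least 1 log2 unit, 14 others had a correlation above 0.95 with the mean of these 2 genes over the 6 hourly means, for which no test was made. They include hypothetical genes such as SIRE_RS09585 (37.5 to 134 CPM from 0 h to 2 h, 1.83 ± 0.13), SIRE_RS06155 (1.68 ± 0.10) and SIRE_RS07055 (1.55 ± 0.11). Others are a winged helix-turn-helix regulator (SIRE_RS09190, 1.32 ± 0.09), a transporter (SIRE_RS00485, 1.53 ± 0.11), an FAD-binding oxidoreductase (SIRE_RS05215, 1.44 ± 0.09), the protein kinase SIRE_RS10350, thymidylate synthase SIRE_RS08520, the origin gene SIRE_RS08850 and MCM. SIRE_RS06225 (1.15 ± 0.11) has the identifier after that of MCM, SIRE_RS06220.

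The genes that fell most at 1 h lay in a single stretch of the chromosome. Of 18 genes at least 8-fold lower, 13 lay within 30 kb, from SIRE_RS03170 to SIRE_RS03350 (601240 to 629085), and the highest number in 10000 random sets of the same size was 5, a one-sided permutation p of 1e-04, the smallest that these sets can give. In this stretch 30 of 32 measured genes were lower at 1 h and 0 higher, and the remaining SIRE_RS03255 (0.16 ± 0.19) and SIRE_RS13820 (-0.22 ± 0.10), were not called. The stretch holds the quinone oxidoreductase subunit genes DoxA (SIRE_RS03270, -3.10 ± 0.22) and DoxD (SIRE_RS03275, -3.48 ± 0.26), 2 hemerythrin domain genes, a universal stress protein (SIRE_RS03235, -1.13 ± 0.08) and a helix-turn-helix gene (SIRE_RS03205, -2.06 ± 0.09). Joint control of this stretch by the acid treatment or the block is a hypothesis that these samples do not test, since every later hour lacked both.

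The first pattern is the step from 0 h to 1 h, with 1487 calls. With libraries scaled to totals alone, 42.3% of the calls were higher (614 higher, 838 lower) and the median of all tested genes was -0.049. A larger share for a few abundant genes would lower all others alike, so it can account for a small shift down but not for the 614 genes that were higher. With every library thinned to 2896709 counts, 1445 genes were called, which argues against a difference in depth as the source. Removal of the acid, washing, fresh medium and passage out of G2 all began at the same moment and stay open, as untested.

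The second pattern is that 3 of 3 division, 3 of 3 origin and 4 of 5 dNTP supply genes rose at 2 h, while of 16 replication fork genes 7 rose and 5 fell (median 0.13), with a median of 0.564 over all 27. With totals alone, the median over all 27 was 0.449. On that scale a few abundant genes would raise all others only by losing share. The 10 most abundant took 8.67 points more of the counts at 2 h (30.97 ± 0.76%, mean and SD) than at 0 h (22.3 ± 0.53%). This argues against them as the source of the rise with totals alone. The median of 0.564 is on the TMM scale, which already offsets such shares, so the shares say nothing about it. A general outgrowth in fresh medium cannot be told apart from passage through the cell cycle: the ribosomal protein median was only 0.055 (SD over genes 0.273, and -0.059 with totals alone), but fresh medium could act on the genes that rose without raising ribosomal proteins, and all hours after 0 h were in fresh medium. It may be that the genes that rose follow the cell cycle, a hypothesis that an unsynchronized culture moved to fresh medium would test.

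The third pattern is that 4 h replicate 3 and 5 h replicate 3 stood apart from their groups in ribosomal protein levels and in the rRNA share of counts, each towards the other hour. An exchange of these labels cannot be told apart from variation between libraries. Positions were taken on a line from the other 4 h libraries (0) to the other 5 h libraries (1). Over 2411 genes outside the ribosomal list, 4 h replicate 3 and 5 h replicate 3 lay at 0.322 and 0.368. The difference was 0.046, where an exchange would give a negative one, and numbers 1 and 2 gave 0.487 and 0.786. The lines for numbers 1 and 2 ran through groups that included these 2 libraries. For the 65 ribosomal proteins 4 h replicate 3 and 5 h replicate 3 lay at 0.439 and 0.122. From 4 h to 5 h, 255 genes were called without 4 h replicate 3, 650 without 5 h replicate 3 and 634 without both. The gain in calls therefore came with leaving out 5 h replicate 3. A difference between libraries that goes with their share of rRNA cannot be told apart either: within hours, the rRNA share and the ribosomal protein median had r = 0.547 (two-sided permutation p = 0.127) and rho = 0.414 (permutation p = 0.18) over 18 libraries. Without these 2 libraries, also the farthest from the median share, r was -0.554 (permutation p = 0.0794) and rho -0.381 (permutation p = 0.211), so the positive relation rests on them. Among the libraries kept, 1 h replicate 1 also stood apart, at 0.34 for ribosomal proteins against 0.152 and 0.072 in its group. Its rRNA share went the other way, at 0.608% against 0.693 and 0.752%.

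Regrouping the libraries tested whether chance could give as many calls in edgeR. For the time course, 1 of 100 groupings, the real one, gave as many as 2071 genes, and the highest other gave 70. This argues against chance differences between single libraries as the source. Regrouping treats the libraries as independent. If the 3 libraries of an hour shared a culture, it cannot decide about chance differences between cultures. For each of the 9 contrasts 1 of the 10 splits of 6 libraries, the real one, gave the most calls, but 10 splits are too few for a share under 0.05. The highest other split gave 0 calls in 8 contrasts, where the real counts were 1487, 1516, 1521, 1513, 1522, 907, 347 and 336, and other splits had at most 324 genes at an unadjusted p below 0.05. From 4 h to 5 h the real split gave 274, and the split that exchanged 4 h replicate 3 and 5 h replicate 3 gave 177.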
